A study of Mus musculus with 16 samples.

How the data were processed

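RNA from the ventricular myocardium of male mice on a CD1 background, aged 14 weeks, was measured on Affymetrix expression arrays, 1 array per sample. The mice either lacked the adenosine 2A receptor (A2AR) or were wild-type littermates. They had received saline or lipopolysaccharide (LPS, 20 mg/kg, intraperitoneally) 24 h before collection, which gives 4 groups of 4 arrays and 16 arrays in all. RNA had been extracted with Trizol and RNeasy columns and labelled as biotinylated cRNA. The deposited values are log2 probe set summaries that, per the labels, were made with RMA (robust multi-array average, a background correction, quantile normalization and probe summary). The version of RMA, its implementation and the probe set definition are not given in the sources used here. Arrays have no read depth, and their number limits the precision.

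The table held 45101 probe sets with 0 missing values. The 64 control probe sets were left out of the gene tests, 34945 probe sets carried a single gene symbol, 932 carried several symbols and 9160 were unnamed here. Of the single-gene probe sets, 34741 had an Entrez identifier in the reference gene table, whose assembly is GRCm38.p6, and 204 did not. The reference supplied symbols and gene order but no positions, so none are given. For each gene with more than 1 probe set (9010 genes), the probe set with the highest mean over the 16 arrays was used, which left 18193 genes to test. The level of the targeted receptor's own transcript is not reported here, and the planned test of it was not run. The genotype of each array therefore rests on its label, on which every comparison of the genotypes depends.

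The main choices were made before the data were examined. A linear model with 1 mean per group was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow an intensity trend and 12 residual degrees of freedom. P values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called. Errors given with log2 changes are limma standard errors, and errors given with group levels are standard deviations over 4 arrays. All tests are two-sided. The comparisons were LPS against saline in each genotype, knockout against wild-type after each treatment, the mean of both knockout effects, and the difference of the LPS responses between genotypes (the interaction). Because the LPS fold changes of the 2 genotypes share no arrays, they were compared across genes by correlation, with a jackknife over arrays for its spread. Genes are not independent replicates, so that correlation has no p.

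Gene groups were 42 lists fixed beforehand, 27 of processes and 15 of cell type markers, each tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 42 lists of a comparison. Camera compares a list with all other genes. Each list was also tested with the correlation estimated from the data, and members called over all genes tested were counted beside those adjusted over the list alone. The process lists cover adenosine receptors and metabolism, P2 purinergic receptors, cytokines and chemokines, Toll-like receptor and NF-kB signalling, interferon-stimulated genes, acute-phase and secreted innate proteins, complement, MHC class I antigen processing, MHC class II, endothelial activation and coagulation, contractile apparatus, cardiac stress genes, calcium handling and ion channels, adrenergic and cAMP signalling, fatty acid oxidation, glycolysis and glucose uptake, tricarboxylic acid cycle, oxidative phosphorylation, proteolysis and autophagy, oxidative stress and metallothioneins, extracellular matrix and remodelling, apoptosis, necroptosis and pyroptosis, cell cycle, heat shock and unfolded protein response, circadian clock, glucocorticoid-responsive genes, and immediate early genes. The marker lists cover cardiomyocytes, endothelium, fibroblasts, smooth muscle and pericytes, macrophages and monocytes, neutrophils, T and NK cells, B cells, erythroid cells, platelets, atrium, adipocytes, Schwann cells, skeletal muscle, and epicardium and mesothelium.

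Named genes followed a fixed rule. For each LPS comparison these were the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap. For the knockout comparisons, the mean knockout effect and the interaction, every called gene was named with the 5 genes of smallest p that were not called. Up to 3 called members per list with the largest changes could be named, and adenosine receptor genes always. The list members named here were picked from those the rule allows after their values had been seen. Adipoq, Retn, Dbp, Arntl, Myh1 and Slc38a1 in the saline comparison, H2-Aa and Cidec in the comparison after LPS, H2-Aa and Slc38a1 in the interaction, and Slc38a1 in the LPS comparisons fall outside the rule and were chosen after their values had been seen.

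The alternative settings chosen beforehand were the mean of a gene's probe sets, every probe set by itself, dim genes left out (11251 genes with a mean of at least the median over probe sets), variance priors without a trend or with a robust fit, only the arrays compared, the replicate number as a block, a second quantile normalization, centring each array on its median, array weights, a fold change of at least 1.5, an estimated correlation for the lists, and leaving out each array in turn. Added after seeing the data were 3 settings that leave out 2 arrays each, and the lists under both rescalings. Replicate numbers did not pair the arrays: after removal of group means, 24 pairs of arrays with the same number correlated between -0.271 and 0.330, 3 of them over 0.1, so the block was kept as an alternative only.

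The fit was tested on simulated data with the size of these groups, with 500 changed genes at each fold change pooled over 10 simulations. Noise was drawn independently for each gene, with 1 spread per gene pooled over the 4 groups. Only the wild-type LPS comparison and the saline comparison of genotypes were simulated. In the saline comparison of genotypes the fit recovered 15.4% of genes at the smallest fold change simulated, 58.2% at 1.5-fold, 89.8% at 2-fold and 98.2% at 4-fold, and 5.22% of its calls were false. Whether these rates carry over to the real arrays was not tested. Wild-type LPS array 4 and knockout LPS array 2 stood apart there, with array weights of 0.217 and 0.285. Duplicate arrays and sex were checked: 0 of the 16 arrays failed to match the male label, and at least 99.678% of probe sets differed between any 2 arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.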

Results

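Gene expression was measured in mouse ventricular myocardium in a 2 by 2 design that crossed loss of the adenosine 2A receptor (A2AR, a cell surface receptor for adenosine that raises cAMP) with LPS, the bacterial endotoxin used here to provoke systemic inflammation. Each of the 4 groups (wild-type saline, wild-type LPS, knockout saline, knockout LPS) held 4 arrays, and 18193 genes were tested. The first principal component took 66.3% of the variance and parted the LPS from the saline arrays, and the second took 8.60%. Median log2 values were 4.62 to 4.67 in every array. Log2 changes are given with their standard error, and every group mean is over n = 4 arrays.

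The LPS comparisons ask how the heart's transcripts respond to endotoxin with and without the A2AR. After 24 h, the 3 largest rises among called genes were the same in both genotypes. Lcn2, which encodes an iron-siderophore binding protein, rose by 9.28 ± 0.21 on the log2 scale in wild-type hearts and by 9.90 ± 0.21 in knockout hearts. Its saline levels (4.48 and 3.97) lay under the median over probe sets (4.66), so the size of these rises depends on the background, and its LPS levels were 13.76 and 13.87. Among the LPS-responsive genes named below, saline levels under that median in 1 or both genotypes were also those of BC023105, Cxcl2, Cxcl5, Cxcl9, Nlrc5, Cfb, Selp, Ada, S100a8, S100a9, Ngp and Itgam. LPS levels under it were those of Car3, Adipoq, P2ry1 and Bmp10, and the sizes of all these changes carry the same limit. Saa3, an acute-phase apolipoprotein, rose by 9.04 ± 0.19 and 8.96 ± 0.19, and Serpina3n, a serine protease inhibitor, by 6.95 ± 0.17 and 6.72 ± 0.17. The largest fall was that of Car3, a carbonic anhydrase abundant in fat and slow muscle, which fell by 6.20 ± 0.64 in wild-type and by 5.99 ± 0.64 in knockout hearts (-7.07 in wild-type hearts without wild-type LPS array 4). Limma called 3798 genes in wild-type hearts, 1689 higher and 2109 lower, and 4744 in knockout hearts, 2075 higher and 2669 lower. At a fold change of at least 1.5 the counts were 2247 and 2772, and at 2-fold or more 1031 and 1270. LPS and saline arrays did not overlap for 22.8% of genes in wild-type and 28.5% in knockout hearts, where chance gives 2.86%.

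Inflammatory groups rose in both genotypes, as shown in the plot of list means. All 28 measured interferon-stimulated genes rose in wild-type hearts and 27 in knockout hearts, 28 in each when adjusted over the list alone (camera adjusted p = 3.80e-39 and 2.25e-33). Antiviral RNA-binding proteins rose in wild-type and knockout hearts, Ifit1 by 5.94 ± 0.46 and 6.06 ± 0.46 and Ifit3 by 5.69 ± 0.39 and 4.87 ± 0.39. Igtp, an interferon-induced GTPase, rose by 5.11 ± 0.29 and 5.85 ± 0.29. Each of the 12 measured genes of MHC class I antigen processing rose in both genotypes, also when adjusted over the list alone (camera adjusted p = 2.23e-24 and 1.46e-21). Among them were the peptide transporter Tap1 (3.82 ± 0.30 and 3.79 ± 0.30), the immunoproteasome subunit Psmb8 (3.55 ± 0.17 and 3.47 ± 0.17) and the transcriptional activator Nlrc5 (3.99 ± 0.34 and 4.55 ± 0.34). Acute-phase and secreted innate proteins rose for 14 of 19 measured genes in wild-type and 15 in knockout hearts, 15 and 16 adjusted over the list alone (camera adjusted p = 1.49e-24 and 7.05e-22). BC023105, named by its size, rose by 6.56 ± 0.40 and 6.63 ± 0.40.

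Of 30 measured cytokines and chemokines, 20 rose and 1 fell in wild-type hearts, and 19 rose and 3 fell in knockout hearts. Adjusted over the list alone, 22 rose and 1 fell, and 20 rose and 3 fell (camera adjusted p = 8.05e-13 and 1.09e-09). The T cell attractant Cxcl9 rose by 6.45 ± 0.37 and 6.33 ± 0.37, and the neutrophil attractants Cxcl1 (4.51 ± 0.34 and 4.63 ± 0.34), Cxcl2 (4.51 ± 0.67 and 5.13 ± 0.67) and Cxcl5 (4.86 ± 0.96 and 5.80 ± 0.96) rose in both. Without wild-type LPS array 4 the wild-type rises of Cxcl2 and Cxcl5 were 5.47 and 5.97, and without wild-type LPS array 3 that of Cxcl5 was 4.23. The knockout rise of Cxcl5 was 5.21 without knockout LPS array 2 and 6.85 without array 4. Toll-like receptor and NF-kB signalling rose for 16 of 23 genes in wild-type and 19 in knockout hearts, 16 and 20 adjusted over the list alone (camera adjusted p = 1.66e-17 and 5.34e-17). Risers included the bacterial lipoprotein receptor Tlr2 (3.18 ± 0.32 and 3.02 ± 0.32), and the NF-kB regulators Nfkbiz (3.54 ± 0.39 and 4.03 ± 0.39) and Tnfaip3 (2.96 ± 0.35 and 3.22 ± 0.35). Complement rose for 6 of 13 genes in both, 7 and 6 adjusted over the list alone (camera adjusted p = 1.04e-06 and 0.000273). Both complement calls were lost (adjusted p = 0.0647 and 0.177 with an estimated correlation). Cfb, of the alternative pathway, rose by 3.89 ± 0.19 and 3.69 ± 0.19, and C1ra, of the classical pathway, by 2.59 ± 0.15 and 2.41 ± 0.15.

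Endothelial activation and coagulation genes rose for 8 of 16 and fell for 1 in wild-type hearts, and rose for 7 and fell for 2 in knockout hearts. Adjusted over the list alone, 8 rose and 1 fell, and 8 rose and 3 fell (camera adjusted p = 0.00225 and 0.00209). The leukocyte adhesion molecules Selp (3.83 ± 0.38 and 4.09 ± 0.38) and Icam1 (3.20 ± 0.19 and 3.27 ± 0.19) rose. Neutrophil markers rose for 5 of 11 genes in wild-type and 6 in knockout hearts, 6 and 7 adjusted over the list alone (camera adjusted p = 2.60e-06 and 1.11e-06). The granule proteins S100a8 (4.84 ± 0.17 and 5.58 ± 0.17), S100a9 (4.86 ± 0.20 and 4.99 ± 0.20) and Ngp (2.36 ± 0.38 and 3.24 ± 0.38) rose. S100a8 and S100a9 are also in the acute-phase list. Macrophage and monocyte markers did not pass as a list (camera adjusted p = 0.175 and 0.567): 3 of 11 rose in each genotype, and 2 fell in wild-type and 3 in knockout hearts. Adjusted over the list alone, 3 rose and 2 fell, and 3 rose and 4 fell. Mpeg1 (2.65 ± 0.22 and 2.64 ± 0.22) and the integrin Itgam (2.47 ± 0.22 and 2.38 ± 0.22) rose, and Lyz2, a lysozyme, fell by 2.22 ± 0.61 in knockout hearts. In wild-type hearts Lyz2 had a log2 change of -1.31 ± 0.61 (adjusted p = 0.157), and without wild-type LPS array 4 it had one of -2.17 (adjusted p = 0.000256).

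Stress and cell death genes rose too. Oxidative stress and metallothionein genes rose for 13 of 20 in wild-type and 9 in knockout hearts, 13 and 10 adjusted over the list alone (camera adjusted p = 6.71e-09 and 1.05e-07). The metal-binding proteins Mt2 (5.60 ± 0.32 and 5.57 ± 0.32) and Mt1 (2.70 ± 0.16 and 2.90 ± 0.16) rose. Genes of apoptosis, necroptosis and pyroptosis rose for 13 of 20 in wild-type hearts, and rose for 14 and fell for 1 in knockout hearts. With p adjusted over the list alone, 15 rose, and 15 rose and 1 fell (camera adjusted p = 6.65e-11 and 3.77e-09). The LPS-sensing caspase Casp4 (3.07 ± 0.27 and 2.94 ± 0.27), the necroptosis effector Mlkl (2.38 ± 0.26 and 2.72 ± 0.26) and the cell cycle inhibitor Cdkn1a (3.35 ± 0.28 and 4.14 ± 0.28) rose. Proteolysis and autophagy genes rose for 9 of 16 and 8 of 16, 10 rising in wild-type, and 9 rising and 1 falling in knockout hearts, when adjusted over the list alone (camera adjusted p = 2.85e-07 and 0.000173). Glucocorticoid-responsive genes rose for 9 of 13 in each, 10 and 9 adjusted over the list alone (camera adjusted p = 3.69e-12 and 1.10e-10), among them Cebpd (3.06 ± 0.25 and 2.58 ± 0.25) and the lipase inhibitor Angptl4 (3.85 ± 0.64 and 4.51 ± 0.64, and 4.79 in wild-type hearts without wild-type LPS array 4). Immediate early genes rose for 6 of 21 and 8 of 21, 7 and 8 adjusted over the list alone (camera adjusted p = 0.0295 and 0.000203), and both calls were lost (adjusted p = 0.539 and 0.287 with an estimated correlation). The transcription factors Junb (2.07 ± 0.38 and 2.60 ± 0.38) and Myc (2.65 ± 0.45 and 2.52 ± 0.45) rose, and without wild-type LPS array 4 the wild-type rise of Myc was 3.27. The wild-type call of that list was also lost without wild-type LPS array 1 (adjusted p = 0.0521), 2 (0.137) or 3 (0.0873) and without wild-type saline array 1 (0.0838) or 2 (0.0884).

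**Figure D1:**
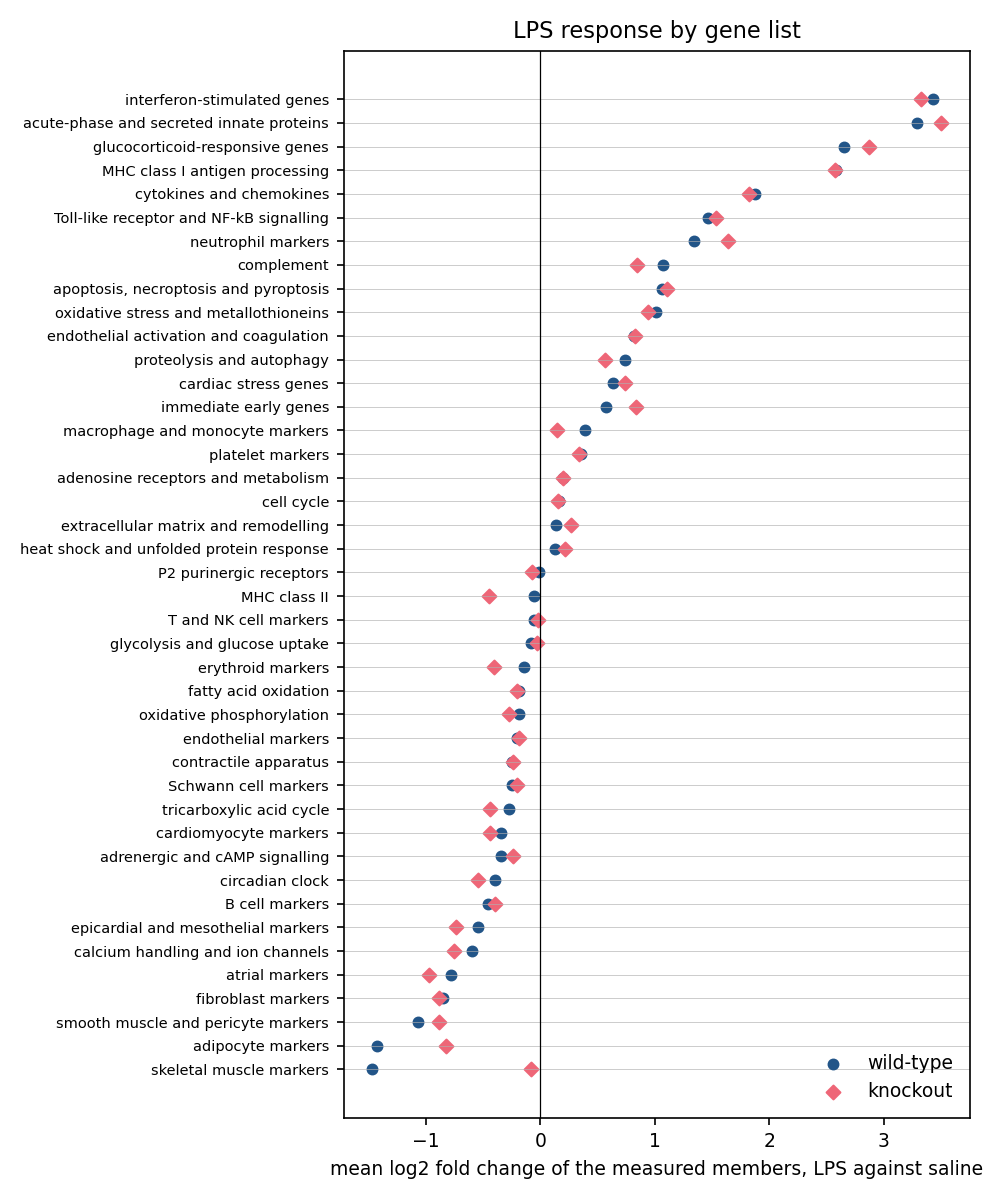
Mean log2 fold change of the measured members of each of the 42 gene lists, LPS against saline, in wild-type (circles) and knockout hearts (diamonds), 4 arrays per group. Interferon-stimulated genes had the largest mean in wild-type hearts (3.43) and acute-phase proteins in knockout hearts (3.50), and skeletal muscle markers lay furthest apart between the genotypes (-1.47 and -0.08).

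Genes of contraction and ion handling fell in part. Of 19 contractile apparatus genes, 9 fell in wild-type and 7 in knockout hearts. When adjusted over the list alone, 11 fell in wild-type, and 8 fell and 1 rose in knockout hearts (camera adjusted p = 3.46e-05 and 0.000670, lost at adjusted p = 0.151 and 0.241 with an estimated correlation). The Z-disc protein Ldb3 fell by 0.73 ± 0.14 and 1.03 ± 0.14, and cardiac actin, Actc1, by 0.66 ± 0.09 and 0.81 ± 0.09. Calcium handling and ion channel genes fell for 13 of 23 and rose for 1 in wild-type hearts, and fell for 16 in knockout hearts. With p adjusted over the list alone, 14 fell and 1 rose, and 18 fell and 1 rose (camera adjusted p = 5.22e-06 and 1.11e-06, lost at adjusted p = 0.148 and 0.152 with an estimated correlation). The potassium channel genes Kcnk3 (-2.06 ± 0.46 and -2.43 ± 0.46) and Kcnj3 (-1.66 ± 0.35 and -2.20 ± 0.35) and the channel subunit Kcnip2 (-1.28 ± 0.25 and -2.19 ± 0.25) fell, Kcnk3 by 2.67 in wild-type hearts without wild-type LPS array 4. Adrenergic and cAMP signalling genes fell for 8 of 17 and rose for 2 in wild-type hearts, and fell for 9 and rose for 4 in knockout hearts. Counts adjusted over the list alone were 10 down and 4 up, and 11 down and 4 up (camera adjusted p = 0.00225 and 0.0237, lost at adjusted p = 0.0585 and 0.168 with an estimated correlation). Pde4b, a phosphodiesterase that degrades cAMP, rose by 2.63 ± 0.57 in knockout and by 1.78 ± 0.57 in wild-type hearts. The wild-type call of Pde4b (adjusted p = 0.0355) was lost in each of the settings that left out 1 wild-type saline array or wild-type LPS array 1, 2 or 3, where adjusted p ran from 0.0580 to 0.120, and without wild-type LPS array 4 its wild-type rise was 2.65 and the call held. Cardiac stress genes did not pass (camera adjusted p = 0.139 and 0.0534): 2 of 8 rose in wild-type and 4 in knockout hearts, 2 and 4 adjusted over the list alone, Ankrd2 by 3.28 ± 0.63 and 3.14 ± 0.63. The knockout rise of Ankrd2 was 2.46 without knockout LPS array 2 and 3.74 without array 4. The sarcomere protein gene Lmod3 fell by 2.35 ± 0.35 and 3.27 ± 0.35.

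Energy metabolism genes fell in part. Tricarboxylic acid cycle genes fell for 7 of 18 in wild-type and 14 in knockout hearts, 9 and 18 adjusted over the list alone (camera adjusted p = 0.000264 and 5.62e-07, lost at adjusted p = 0.393 and 0.241 with an estimated correlation). Dlst fell by 0.55 ± 0.11 and 0.59 ± 0.11, and Pdhb by 0.43 ± 0.12 and 0.68 ± 0.12, though without wild-type saline array 1 the wild-type change of Pdhb was -0.38 (adjusted p = 0.0549). Oxidative phosphorylation genes fell for 10 of 28 and 17 of 28, 11 and 25 adjusted over the list alone (camera adjusted p = 8.19e-06 and 6.98e-08, lost at adjusted p = 0.288 and 0.205 with an estimated correlation). Ndufs7 of complex I fell by 0.39 ± 0.09 and 0.48 ± 0.09. Fatty acid oxidation did not pass (camera adjusted p = 0.191 and 0.0799): 3 of 22 fell in wild-type hearts, and 6 fell and 2 rose in knockout hearts, with 3 falling, and 7 falling and 2 rising, adjusted over the list alone. Ppargc1a, a coactivator of mitochondrial genes, fell by 2.23 ± 0.34 and 1.35 ± 0.34, and Ppara, its nuclear receptor partner, by 1.06 ± 0.22 and 0.65 ± 0.22. Wild-type LPS array 4 was low for Ppargc1a, at 6.48 against 8.35 to 8.66 in the other wild-type LPS arrays. The knockout LPS arrays stood at 8.08 to 8.98, so the larger wild-type fall rests in part on that array. The knockout call of Ppara (adjusted p = 0.0427) was lost without any single saline array of either genotype. It was also lost without knockout LPS array 1, 3 or 4 or wild-type LPS array 2, with a highest adjusted p of 0.146. Glycolysis and glucose uptake genes fell for 8 of 17 and rose for 3 in each genotype. When adjusted over the list alone, 12 fell and 3 rose in wild-type, and 9 fell and 3 rose in knockout hearts (camera adjusted p = 0.00195 and 0.0309, lost at adjusted p = 0.151 and 0.287 with an estimated correlation). The knockout call of that list was lost without knockout LPS array 3 (adjusted p = 0.0731). The glucose transporter Slc2a4 fell by 1.28 ± 0.20 and 1.68 ± 0.20, while Pfkfb3, an activator of glycolysis, rose by 2.69 ± 0.26 and 3.07 ± 0.26 and Pdk4, an inhibitor of pyruvate dehydrogenase, by 1.87 ± 0.38 and 2.17 ± 0.38.

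Markers of several cell types fell. Cardiomyocyte markers, most of which are also in the contractile or calcium lists, fell for 6 of 10 in both, 6 and 7 adjusted over the list alone (camera adjusted p = 0.000230 and 0.000273, lost at adjusted p = 0.0709 and 0.0948 with an estimated correlation). Smooth muscle and pericyte markers fell for 8 of 10 in both, also adjusted over the list alone (camera adjusted p = 1.89e-07 and 4.80e-05, lost at adjusted p = 0.0729 and 0.177 with an estimated correlation). The actin-binding Tagln (-2.09 ± 0.19 and -1.78 ± 0.19) and Cnn1 (-1.85 ± 0.28 and -1.54 ± 0.28) fell. Fibroblast markers fell for 4 of 9 in both, 4 and 5 adjusted over the list alone (camera adjusted p = 0.00195 and 0.00323, lost at adjusted p = 0.340 and 0.326 with an estimated correlation), Lum by 1.78 ± 0.27 and 2.24 ± 0.27. Atrial markers fell for 4 of 5 in both, 4 and 5 adjusted over the list alone (camera adjusted p = 0.000556 and 0.000273, lost at adjusted p = 0.164 and 0.177 with an estimated correlation). Myl7, the atrial myosin light chain, fell by 1.06 ± 0.17 and 1.18 ± 0.17, and Bmp10 by 1.10 ± 0.28 and 1.63 ± 0.28. Adipocyte markers fell for 4 of 6 in wild-type and 2 in knockout hearts, 4 and 2 adjusted over the list alone, and the list passed in wild-type hearts (camera adjusted p = 0.000131) and not in knockout hearts (0.0694). The adipokine Adipoq fell by 4.27 ± 0.40 and 3.33 ± 0.40. Skeletal muscle markers fell for 1 of 8 in wild-type hearts and 0 in knockout hearts, 7 and 0 adjusted over the list alone. Camera gave adjusted p = 0.00566 and 0.730, the first lost at adjusted p = 0.343 with an estimated correlation. Wild-type saline arrays 1 and 4 had skeletal marker means of 5.88 and 7.57, against 3.75 to 3.97 in the other arrays, and without them the mean change of the list in wild-type hearts went from -1.47 to -0.07 (adjusted p = 0.385). It was -0.72 without array 4 alone. MHC class II genes rose for 1 of 7 and fell for 1 in wild-type hearts and fell for 4 in knockout hearts, with the same numbers adjusted over the list alone (camera adjusted p = 0.833 and 0.0435, the second lost at adjusted p = 0.205 with an estimated correlation). H2-Aa, an antigen-presenting chain, fell (-0.99 ± 0.16 and -1.60 ± 0.16). The knockout call of MHC class II was lost without knockout LPS array 2 (adjusted p = 0.0890) or 4 (0.0633), knockout saline array 1 (0.0512) or wild-type LPS array 4 (0.0573).

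The other lists did not pass in either genotype. Adenosine receptors and metabolism had 3 genes up and 3 down of 11 in wild-type and 4 up and 3 down in knockout hearts, the same adjusted over the list alone (camera adjusted p = 0.642 and 0.562). Ada, which deaminates adenosine, rose by 1.61 ± 0.25 and 1.52 ± 0.25, and Pnp, which splits inosine, by 1.24 ± 0.14 in both, while the adenosine receptor Adora3 had log2 changes of -0.01 ± 0.10 and 0.04 ± 0.10 (adjusted p = 0.947 and 0.821). P2 purinergic receptors had 4 up and 2 down of 14, and 2 up and 3 down, and adjusted over the list alone 5 and 3, and 3 and 3 (camera adjusted p = 0.925 and 0.738). P2ry1 fell (-1.24 ± 0.22 and -1.62 ± 0.22) and P2ry2 rose by 1.22 ± 0.33 and 1.24 ± 0.33. The wild-type call of P2ry2 was lost without wild-type LPS array 2 (adjusted p = 0.0505), wild-type saline array 3 (0.0514) or wild-type LPS array 1, where the change was 1.04. Extracellular matrix genes had 7 up and 9 down of 27, and 8 up and 7 down, and adjusted over the list alone 10 and 9, and 8 and 10 (camera adjusted p = 0.833 and 0.538). Timp1, a metalloproteinase inhibitor (4.32 ± 0.22 and 4.62 ± 0.22), Mmp3 (3.50 ± 0.37 and 3.60 ± 0.37) and the crosslinking enzyme Lox (3.20 ± 0.27 and 3.91 ± 0.27) rose. Circadian clock genes had 1 up and 5 down of 16, and 1 up and 7 down, the same adjusted over the list alone (camera adjusted p = 0.0819 and 0.0640). The clock output genes Dbp (-1.82 ± 0.44 and -2.86 ± 0.44), Hlf (-1.89 ± 0.23 and -2.12 ± 0.23) and Per3 (-1.36 ± 0.36 and -2.10 ± 0.36) fell. Without wild-type saline arrays 3 and 4, whose clock genes lay apart, their wild-type changes were -2.70, -2.24 and -1.87. Endothelial markers had 1 up and 2 down of 11, and 1 up and 3 down, the same adjusted over the list alone (camera adjusted p = 0.349 and 0.515). Emcn fell by 0.94 ± 0.22 in knockout and by 0.69 ± 0.22 in wild-type hearts, the latter call (adjusted p = 0.0355) being lost without any single wild-type saline array or wild-type LPS array 1, 2 or 3 (adjusted p from 0.0523 to 0.112). Epicardial and mesothelial markers fell for 2 of 6 in both, also adjusted over the list alone (camera adjusted p = 0.175 and 0.0694), Upk3b by 1.93 ± 0.40 and 2.47 ± 0.40.

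Camera gave adjusted p = 0.571 and 0.738 for cell cycle genes, of which 2 of 21 rose in wild-type hearts and 1 rose and 1 fell in knockout hearts, 1 rising, and 1 rising and 1 falling, adjusted over the list alone. Heat shock and unfolded protein response genes had 5 up and 3 down of 16, and 6 up and 4 down, and adjusted over the list alone 5 and 4, and 6 and 4 (adjusted p = 0.201 and 0.0527). T and NK cell markers had 1 up and 2 down of 10, and 0 up and 1 down, and adjusted over the list alone 2 and 2, and 0 and 1 (adjusted p = 0.918 and 0.784). B cell markers fell for 1 of 6 in both, also adjusted over the list alone (adjusted p = 0.134 and 0.257), and erythroid markers for 0 and 1 of 3, also adjusted over the list alone (adjusted p = 0.984 and 0.674). Platelet markers had 1 up of 6 in wild-type, and 1 up and 1 down in knockout hearts, also adjusted over the list alone (adjusted p = 0.191 and 0.701). Schwann cell markers fell for 1 of 3 in both, also adjusted over the list alone (adjusted p = 0.145 and 0.285). Median, mean and test differed in sign for MHC class II in wild-type hearts (0.04, -0.05 and down) and for the extracellular matrix (-0.01, 0.14 and up in wild-type, -0.05, 0.27 and up in knockout hearts). They also did for the cell cycle (-0.02, 0.16 and up) and for T and NK cells (0.04, -0.02 and up) in knockout hearts.

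With an estimated correlation, 12 of the 25 wild-type and 11 of the 24 knockout list calls held, namely interferon, acute-phase, MHC class I, Toll-like receptor, cytokine, endothelial activation, neutrophil, oxidative stress, cell death, proteolysis and glucocorticoid lists in both, and adipocyte markers in wild-type hearts. Among the remaining large falls, Aplnr, the apelin receptor, fell by 4.08 ± 0.36 and 4.09 ± 0.36 and the integrin Itga8 by 3.17 ± 0.25 and 2.96 ± 0.25. The transporter Abca8a fell by 3.14 ± 0.44 and 3.63 ± 0.44, and C1qtnf9 by 3.05 ± 0.55 and 3.83 ± 0.55 (-3.86 in wild-type hearts without wild-type LPS array 4). Penk, an opioid precursor, fell by 3.05 ± 0.22, Itih5 by 3.05 ± 0.25 in wild-type hearts, and the lectin Colec11 by 4.20 ± 0.67 and the methyltransferase Inmt by 3.58 ± 0.41 in knockout hearts. For each of these genes, all LPS arrays of the other genotype also lay below its saline arrays. The LPS response of each array was scaled to the mean response of the other genotype, over genes called there. On that scale wild-type LPS array 4 reached 57.1%, against 85.8% to 104% in the other wild-type LPS arrays. Knockout LPS arrays, scaled to a wild-type mean that includes wild-type LPS array 4, reached 89.3% to 109%. Knockout LPS array 2 had the largest 3' minus 5' difference of Gapdh (0.90, against 0.01 to 0.16 in the other LPS arrays). Without wild-type LPS array 4 and knockout LPS array 2, 5723 genes were called in wild-type and 5373 in knockout hearts. Without wild-type saline arrays 1 and 4 the counts were 2061 and 4191, and without wild-type saline arrays 3 and 4, whose clock genes lay apart, 2295 and 4312.

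The LPS responses of both genotypes were then set side by side. Across all genes the LPS fold changes correlated with a Pearson r of 0.921 (jackknife standard error 0.030) and a Spearman rho of 0.763, and r was 0.957 among the 5531 genes called in either genotype, as the scatter of both responses shows. Called in both and higher in both were 1337 genes, where independence gives 193, and lower in both were 1674, where it gives 309. No gene was called in opposite directions (0, where independence gives 488). Of 787 genes called in wild-type hearts alone, 733 had the same sign in knockout hearts, and of 1733 called in knockout hearts alone, 1621 had the same sign in wild-type hearts.

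**Figure D2:**
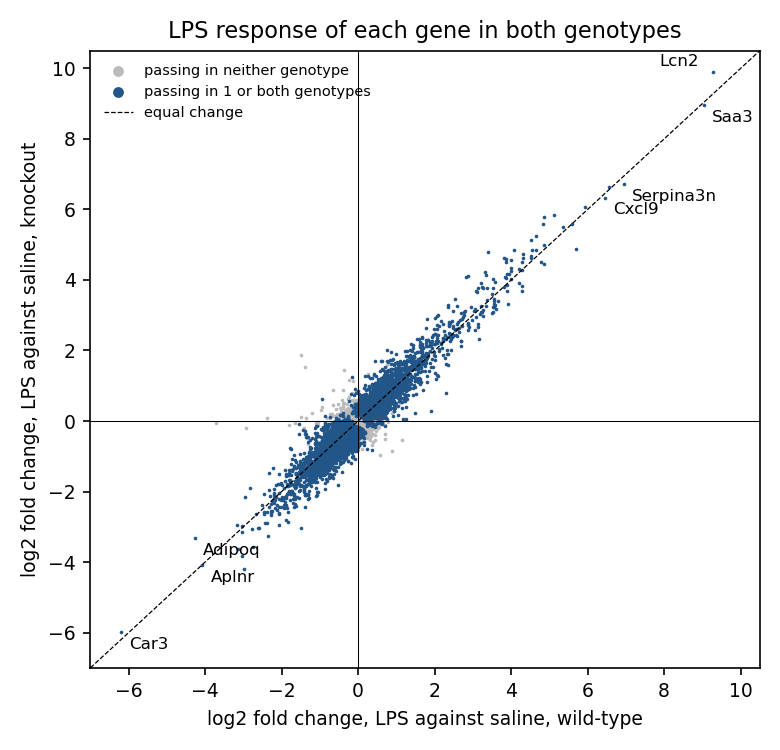
Each point is 1 of 18193 genes, with the log2 fold change of LPS against saline in wild-type hearts on the horizontal axis and in knockout hearts on the vertical axis, blue where it passed in 1 or both genotypes. Points lie along the dashed line of equal change (Pearson r 0.921 across genes), from Car3 (-6.20 and -5.99) to Lcn2 (9.28 and 9.90).

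The interaction asks whether loss of the A2AR altered the LPS response. Limma called 0 genes (813, or 4.47%, at an unadjusted p under 0.05), and 0 in every setting that left out the doubted arrays. The genes of smallest p did not pass: Cidec had an interaction of 0.95 ± 0.18, Txndc11 of 0.95 ± 0.19, Rbfox1 of -0.79 ± 0.16 and Nectin3 of 1.00 ± 0.21 (adjusted p = 0.757 for each), and Atp6v0d2 of -0.36 ± 0.08 (adjusted p = 0.959). Adora3 had one of 0.05 ± 0.14 (adjusted p = 0.984) and Slc38a1 of 0.64 ± 0.22 (adjusted p = 0.959). Cidec stood at 4.354 to 4.97 in the wild-type saline arrays and at 3.278 to 3.748 in all other arrays, under the median over probe sets. Its interaction therefore reflects its saline levels and depends on the background. As lists, MHC class II had a lower LPS response in knockout than in wild-type hearts, where the list did not pass (mean difference -0.40, camera adjusted p = 0.000936), with 0 of 7 members called and 3 lower when adjusted over the list alone, and H2-Aa at -0.61 ± 0.23 (adjusted p = 0.959). Tricarboxylic acid cycle (mean -0.16, camera adjusted p = 0.00665) and oxidative phosphorylation genes (-0.09, 0.0445) were lower, and immediate early genes (0.26, 0.0168), adipocyte markers (0.61, 0.000904) and skeletal muscle markers (1.39, 0.000904) higher. Over all genes 0 of these members were called, and adjusted over the list alone 1 adipocyte marker was higher. All 6 calls were lost (adjusted p = 0.162 for MHC class II and for adipocytes, 0.868 for skeletal muscle and 0.891 for the others with an estimated correlation). The skeletal difference was -0.01 without wild-type saline arrays 1 and 4 (adjusted p = 0.855) and 0.64 without array 4 alone, and that of immediate early genes 0.02 without wild-type LPS array 4 (adjusted p = 0.963). The tricarboxylic acid cycle call was lost without knockout LPS array 2 (mean -0.05, adjusted p = 0.370), wild-type LPS array 4 (-0.13, 0.0622) or knockout saline array 2 (-0.13, 0.0503). That of immediate early genes was also lost without knockout LPS array 1 (0.155) or 2 (0.0581), knockout saline array 2 (0.0862) or wild-type saline array 3 (0.139). That of oxidative phosphorylation was lost without knockout LPS array 1 (0.0778), 2 (0.406) or 3 (0.109), knockout saline array 2 (0.0862) or 4 (0.0876), wild-type LPS array 1 (0.116) or 4 (0.279), or wild-type saline array 2 (0.0578) or 3 (0.139). The adipocyte list means of wild-type and knockout hearts were 6.287 and 5.532 after saline and 4.857 and 4.711 after LPS. That interaction thus lay mainly in the saline levels. The other 36 lists did not pass, with adjusted p from 0.0526 to 0.904.

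The saline comparison asks what loss of the A2AR does to the unstimulated heart, with genotypes taken from the labels and not checked in the arrays. Cidec, which encodes a lipid droplet protein of fat cells, was the gene called: it fell by 1.04 ± 0.13 in knockout hearts (2.05-fold, adjusted p = 0.00500). Its level was 4.65 ± 0.27 (SD, n = 4) in wild-type and 3.61 ± 0.14 (SD, n = 4) in knockout hearts, with all 4 knockout arrays below all 4 wild-type arrays. Both levels lay under the median over probe sets (4.66), so the fold depends on the background. Adipocyte markers fell as a list (mean -0.76, camera adjusted p = 1.32e-11, and adjusted p = 0.00527 with an estimated correlation), with 1 of 6 members lower over all genes and 4 adjusted over the list alone. The adipokines Adipoq and Retn had log2 differences of -1.32 ± 0.40 (adjusted p = 1.00) and -0.73 ± 0.18 (adjusted p = 0.774). At an unadjusted p under 0.05, limma gave 634 genes (3.48%), and groups did not overlap for 3.89% of genes, where chance gives 2.86%. The variance of each gene was shared with the LPS groups, whose arrays varied more, so the saline test can be too strict. The next genes did not pass: Ptger3 at -0.56 ± 0.09 (adjusted p = 0.0635), Tslp at 0.70 ± 0.12 (0.0778), Pon1 at -0.75 ± 0.13 (0.0929), Pde3b at -0.81 ± 0.15 (0.167) and the haemoglobin-binding Hp at -1.41 ± 0.26 (0.167). Adora3 was at -0.17 ± 0.10 (adjusted p = 1.00) and Slc38a1 at 0.55 ± 0.16 (0.909).

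Clock genes were higher in knockout saline hearts as a list (mean 0.30, camera adjusted p = 0.000172, and adjusted p = 0.0634 with an estimated correlation), with 0 of 16 called and, adjusted over the list alone, 9 higher and 2 lower. Dbp had a difference of 1.22 ± 0.44 (adjusted p = 1.00) and the clock activator Arntl of -1.58 ± 0.36 (adjusted p = 0.566). Wild-type saline arrays 3 and 4 lay apart in these genes, and without them the mean of the list was 0.12 (adjusted p = 0.226). Skeletal muscle markers were lower as a list (mean -1.42, camera adjusted p = 1.14e-09, and adjusted p = 0.174 with an estimated correlation), with 0 of 8 called and 6 lower adjusted over the list alone. Myh1, a fast skeletal myosin, stood at 9.0 and 11.37 in wild-type saline arrays 1 and 4, and its difference was -3.65 ± 1.31 (adjusted p = 1.00). Without both arrays the list mean was -0.03 (adjusted p = 0.662), and without array 4 alone -0.67. Heat shock genes (-0.17, camera adjusted p = 0.00446) and immediate early genes (-0.21, 0.00446) were lower as lists, and platelet (0.23, 0.00945) and atrial markers (0.22, 0.0340) higher, with 0 members called and 1 platelet marker higher adjusted over the list alone. These 4 calls were lost (adjusted p = 0.251, 0.976, 0.251 and 0.798 with an estimated correlation). Without wild-type saline array 3 the heat shock and immediate early calls were lost (adjusted p = 0.0613 and 0.159). The heat shock call was also lost without wild-type saline array 4 (0.0747) and the immediate early call without knockout saline array 2 (0.0620). Without wild-type saline array 1 the atrial mean was 0.05 (adjusted p = 0.787). The atrial call was also lost without knockout saline array 1 (0.0920) or 3 (0.116). The other 35 lists did not pass, with adjusted p from 0.0911 to 0.986. The number of called genes was 9 without the 2 LPS arrays of lowest weight, 1 without wild-type saline arrays 1 and 4, and 0 without wild-type saline arrays 3 and 4, where Cidec was at -0.83 (adjusted p = 0.198). It was 14 with only the arrays compared, 21 with array weights and 0 with dim genes, Cidec among them, left out. Leaving out 1 array gave 5 without knockout saline array 3, 3 without knockout saline array 1, wild-type LPS array 4 or knockout LPS array 4, and 2 without knockout LPS array 2.

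**Figure D3:**
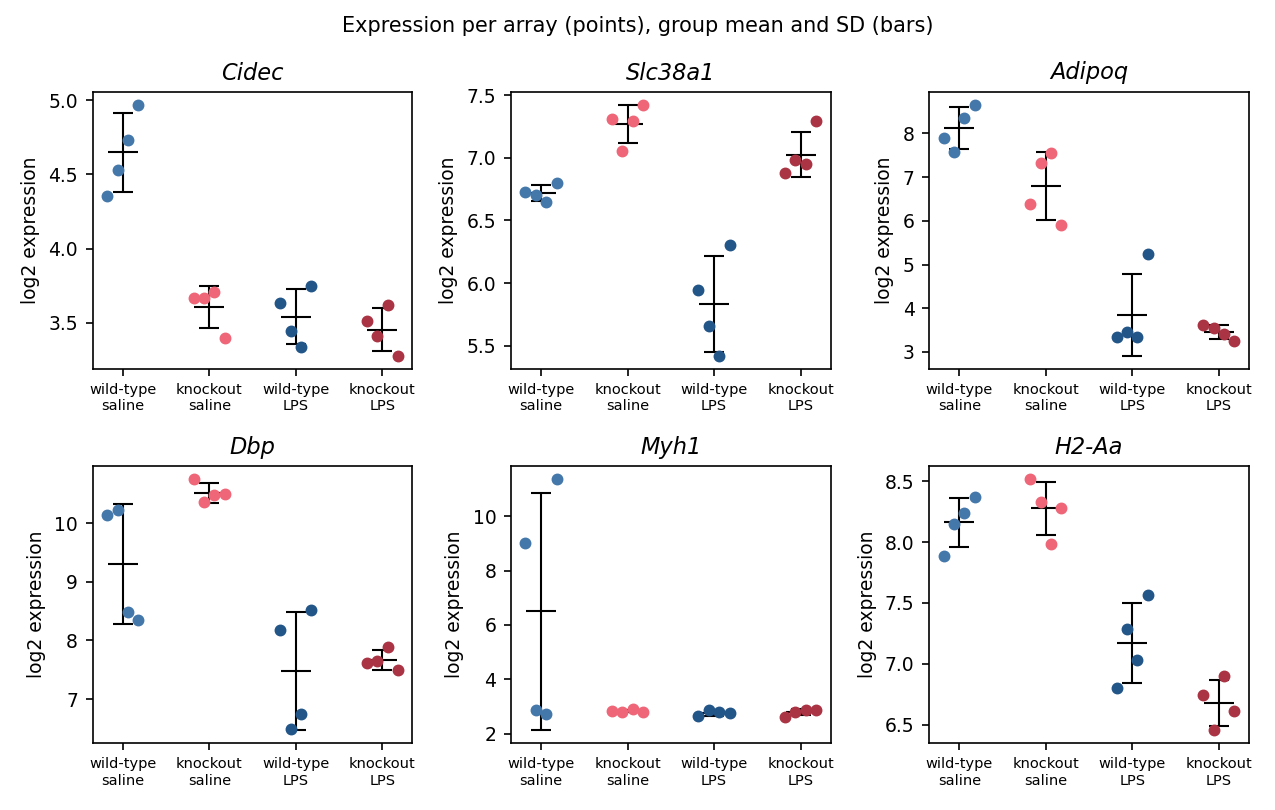
Log2 expression per array (points) with group mean and SD (bars, n = 4) for 6 genes in the 4 groups, each panel with its own axis. All 4 knockout saline arrays lay below the wild-type saline arrays for Cidec, and Myh1 was high in 2 wild-type saline arrays (9.0 and 11.37).

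The comparison after LPS asks the same of the endotoxemic heart. Slc38a1, a glutamine transporter gene, was higher in knockout than in wild-type hearts by 1.19 ± 0.16 (2.29-fold, adjusted p = 0.0145), at 7.03 ± 0.18 (SD, n = 4) against 5.83 ± 0.38 (SD, n = 4). With LPS it fell by 0.89 in wild-type hearts (adjusted p = 0.000568) and did not pass in knockout hearts (-0.25, adjusted p = 0.287). It was the gene called, and limma gave 1375 genes (7.56%) at an unadjusted p under 0.05, while groups did not overlap for 2.26% of genes, where chance gives 2.86%. The fit shares 1 variance per gene over the 4 groups, although LPS arrays varied more. The lowest correlation between arrays of a group was 0.970 for LPS and 0.991 for saline. The test after LPS can therefore be too lenient. The Slc38a1 call was lost without wild-type LPS array 2 (adjusted p = 0.109), knockout LPS array 2 (0.0543) or knockout LPS array 4 (0.0659), and with only the arrays compared (0.966). Genes that did not pass were the imprinted RNA Snhg14 at 1.91 ± 0.31 (adjusted p = 0.107), the splicing factor Rbfox1 at -0.65 ± 0.12 (0.196), Paqr7 at 0.70 ± 0.13 (0.321), Snhg11 at 0.51 ± 0.10 (0.324) and the adhesion molecule Nectin3 at 0.72 ± 0.15 (0.324). Cidec had a difference of -0.09 ± 0.13 (adjusted p = 0.883) and Adora3 of -0.11 ± 0.10 (0.779).

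After LPS, MHC class II genes were lower in knockout hearts as a list (mean -0.36, camera adjusted p = 0.00132, and adjusted p = 0.221 with an estimated correlation), with 0 of 7 called and 3 lower adjusted over the list alone. H2-Aa was at -0.49 ± 0.16 (adjusted p = 0.625). Complement (-0.26, camera adjusted p = 0.0236), tricarboxylic acid cycle (-0.14, 0.0121), oxidative phosphorylation (-0.09, 0.0121) and epicardial markers (-0.40, 0.0159) were lower as lists and neutrophil markers higher (0.32, 0.0121). Over all genes 0 members were called, and adjusted over the list alone 1 epicardial marker was lower and 1 neutrophil marker higher. These 5 calls were lost (adjusted p = 0.893, 0.917, 0.917, 0.501 and 0.501 with an estimated correlation). Without wild-type LPS array 4 the complement mean was -0.10 (adjusted p = 0.212), and without knockout LPS array 2 those of complement, the tricarboxylic acid cycle and oxidative phosphorylation were -0.12 (0.342), -0.02 (0.610) and -0.04 (0.342). Without both arrays the complement and tricarboxylic acid cycle means turned to 0.04 (0.710) and 0.01 (0.882). The neutrophil call was lost without wild-type LPS array 2 (adjusted p = 0.0582). Calls were also lost for complement without knockout LPS array 4 (0.0561) or wild-type LPS array 2 (0.0630), for the tricarboxylic acid cycle without wild-type LPS array 4 (0.0593), and for oxidative phosphorylation without knockout LPS array 3 (0.0715) or wild-type LPS array 1 (0.0586) or 4 (0.168). The epicardial call was lost without knockout LPS array 3 (0.0803) or 4 (0.0707) or wild-type LPS array 1 (0.0586) or 4 (0.0677). The other 36 lists did not pass, with adjusted p from 0.0952 to 0.985. Without the 2 LPS arrays of lowest weight 1 gene was called, and without either pair of wild-type saline arrays 0 were called. Saline arrays enter this comparison only through the variance, and the adjusted p of Slc38a1 was then 0.0764 and 0.0752.

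Averaged over both treatments, Slc38a1 was 0.87 ± 0.11 higher in knockout hearts (1.83-fold, adjusted p = 0.00934) and was the gene called, with 937 genes (5.15%) at an unadjusted p under 0.05. Those not passing were Cidec at -0.56 ± 0.09 (adjusted p = 0.0614), the methionine synthase Mtr, higher in knockout hearts by 2.38-fold (0.0614), Pde3b at -0.63 ± 0.11 (0.0806), Gstp1 at -0.49 ± 0.09 (0.119) and Isy1 at 1.05 ± 0.19 (0.122), with Adora3 at -0.14 ± 0.07 (0.952). Isy1 stood at 5.345 in knockout saline array 3, against 5.28 to 5.82 in wild-type and 6.21 to 7.01 in the other knockout arrays. Gstp1 stood there at 12.25, against 11.75 to 12.23 and 11.21 to 11.70. Without that array both were called after saline, after LPS and on average. For Slc38a1, Cidec, Mtr and Pde3b it lay with the other knockout saline arrays. Its genotype was not checked beyond the label. As lists, adipocyte (mean -0.45, camera adjusted p = 2.54e-06), skeletal muscle (-0.73, 0.000193), epicardial (-0.30, 0.00134), MHC class II (-0.17, 0.0304) and erythroid markers (-0.35, 0.0359) were lower. Clock (0.22, 0.000193), neutrophil (0.18, 0.0217), platelet (0.22, 0.0285) and cell death genes (0.10, 0.0359) were higher. Adjusted over the list alone, 3 adipocyte, 1 skeletal muscle and 2 erythroid markers were lower, 1 neutrophil and 1 platelet marker higher, and 1 clock gene was higher and 1 lower, with 0 members called over all genes. The skeletal mean was -0.36 without wild-type saline array 4 and -0.03 without arrays 1 and 4 (adjusted p = 0.587). All 9 calls were lost (adjusted p = 0.0592, 0.396, 0.257, 0.305 and 0.454 for the lower lists and 0.0614, 0.305, 0.305 and 0.664 for the higher with an estimated correlation). Leaving out 1 array ended the MHC class II call without knockout LPS array 2 (0.0681) or 4 (0.0633), knockout saline array 3 (0.0963) or wild-type LPS array 2 (0.0563) or 4 (0.0567), and the platelet call without knockout LPS array 2 (0.0975) or wild-type LPS array 4 (0.0815). It ended the cell death call without knockout LPS array 1 (0.101) or 2 (0.222), knockout saline array 1 (0.158), wild-type LPS array 1 (0.153) or 4 (0.272) or wild-type saline array 1 (0.0860). It ended the erythroid call without knockout LPS array 3 (0.0699) or 4 (0.133), knockout saline array 1 (0.0557) or 2 (0.0849), wild-type LPS array 3 (0.105) or 4 (0.0815) or wild-type saline array 1 (0.0860). The other 33 lists did not pass, with adjusted p from 0.0571 to 0.973. The knockout effects after saline and after LPS correlated across genes with r = 0.043. Without the 2 LPS arrays of lowest weight 7 genes were called. Without wild-type saline arrays 1 and 4 or 3 and 4, which leaves fewer arrays, 0 were called, and Slc38a1 was at 0.90 (adjusted p = 0.0868) and 0.87 (0.178). Of the 200 measured genes nearest the targeted gene in the reference's order, 100 on each side, 0 were called and 6 (3.00%) had an unadjusted p under 0.05 in this comparison, against 5.17% of the other genes (Fisher's exact p = 0.198). After saline 0 were called and 12 of the 200 had an unadjusted p under 0.05, against 3.46% of the other genes (Fisher's exact p = 0.0756), and after LPS 0 and 10, against 7.59% (Fisher's exact p = 0.224).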

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

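The tests of genotype on the clock score, of RNA degradation in 2 LPS arrays and of mixing in 1 of them, and the settings that leave out 2 arrays, were chosen only after the results had been seen.

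The adipocyte list was lower in knockout than in wild-type hearts after saline. Differing clock phase as the whole cause cannot be decided by a fit with a clock score per array as a covariate. There the list kept camera p = 6.36e-09 at the preset inter-gene correlation. Its mean went from -0.76 to -0.82, and Cidec stood at -0.96 ± 0.16. The LPS arrays also set the clock slope, and only 1 wild-type saline array lay within the knockout range of clock scores. Among the wild-type saline arrays the list mean did not follow the clock score. Arrays 1 and 2 (scores 3.107 and 2.797) had means of 6.383 and 6.117, and arrays 3 and 4 (1.111 and 0.964) of 6.106 and 6.542. More adipose tissue attached to wild-type hearts is a candidate explanation. In all, 17 other adipose genes had a median difference of -0.202, 14 of them lower and 2 with groups that did not overlap (camera p = 2.76e-08, and 0.00308 with an estimated correlation). The differences were uneven, from -1.171 to 0.027. Lower by more than 0.5 were 5 genes: Fasn (-1.171), Scd1 (-0.872), Pnpla3 (-0.767), Thrsp (-0.566) and Pck1 (-0.563). Within 1 standard error of 0 were 7: Acvr1c, Trarg1, Lipe, Dgat2, Agpat2, Aqp7 and Elovl3. A change in some lipid genes alone therefore stays open. Lower food intake of knockout mice cannot be told apart, because genes raised by fasting had a median difference of -0.021 within a spread of -0.25 to 0.26, with 4 of 9 higher (camera p = 0.544 at the preset inter-gene correlation). The rule set beforehand took a median of 0 or below as counting against it, but these quartiles lay on both sides of 0. Genes lowered by fasting were not examined as a group, so whether the 5 genes named above follow feeding was not tested. An effect of genotype on heart or fat cells stays open and was not tested.

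Clock genes differed between saline arrays, with wild-type arrays 3 and 4 apart from the rest. Rhythmic genes outside the list had a score that followed the clock score over the 8 saline arrays (Pearson r = 0.957, exact permutation p = 0.000694, Spearman rho = 0.857, exact permutation p = 0.0107, and r = 0.844 without the 2 arrays farthest from the median). The permutation took both genotypes as 1 group. A difference in the time of collection would give this, but so would any other shift of the clock, so its cause is not decided. An effect of genotype cannot be told apart from the time of collection, since the clock scores differed by 1.38 between genotypes (exact permutation p = 0.0571) and 1 wild-type array lay within the knockout range.

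Wild-type LPS array 4 and knockout LPS array 2 stood apart from their groups, with array weights of 0.217 and 0.285. RNA degradation was argued against in the first, whose 3' minus 5' difference of Gapdh was 0.142, within the 0.01 to 0.90 of the other LPS arrays, and is a candidate explanation in the second, at 0.899 against a highest other value of 0.16, with Actb at 1.74 against 1.52. Mixing of the first with RNA of an unstimulated heart cannot be told apart from an uneven response. A mixture would lie between saline and LPS levels, and 118 of its genes lay more than 1 log2 unit outside the span of the other arrays of its genotype, above the 3 to 37 of the other wild-type LPS arrays and below the 181 of knockout LPS array 2, while the spread of its share of the rise over 50 genes, on unlogged values and relative to the median, was 1.28 (above the next array by 0.349, bootstrap SD 0.372). No biological explanation was tested.

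Other splits of the arrays into groups of 4 were tried for each count. For LPS, 1 of 35 splits in wild-type hearts gave as many genes (3798, highest other 2) and 1 of 35 in knockout hearts (4744, highest other 0), the real split in each. No smaller share is possible with 35 splits, so the splits alone do not exclude chance. Every other split mixes LPS with saline arrays, which widens the spread within groups, so the gap in counts does not measure chance. For knockout against wild-type chance cannot be excluded. After saline, 3 of 35 splits called as many genes (1, highest other 1) and 3 of 35 gave as many at an unadjusted p under 0.05 (634, highest other 902). After LPS 11 of 35 (1, highest other 756) and 22 of 35 (1375, highest other 3672) did. The split with 756 genes set wild-type arrays 1 and 4 and knockout arrays 3 and 4 against the rest. As shares of the other genotype's LPS response, the wild-type arrays stood at 85.8% and 57.1% against 100% and 104%. The knockout arrays stood at 103% and 89.3% against 105% and 109%. The split thus parted the wild-type arrays by their share, while knockout arrays 3 and 1 lay close, at 103% and 105%. That split was picked for its count, and whether the shares underlie it was not tested. For the averaged effect 12 of 100 drawn splits called as many genes (1, highest other 98) and 39 gave as many at an unadjusted p under 0.05 (937, highest other 3139). For the interaction a count of 0 tests nothing, since 100 of 100 splits reach it (highest other 9), and 51 gave as many at an unadjusted p under 0.05 (813, highest other 2180), where chance cannot be excluded.

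Single arrays lay far from the other 3 of their group in 40 of 572 groups examined (6.99%, where chance gives about 1 in 20), 32 for genes and 8 for list means, 14 of them in wild-type LPS array 4 and 4 in knockout LPS array 2. Wild-type LPS array 4 was low for Mt1 (13.17), Mt2 (11.22), Lox (8.04), Angptl4 (6.62), Junb (6.70), Myc (5.52), Pde4b (6.86), Ppargc1a (6.48), Pdk4 (12.34), Ngp (5.28) and the mean of glucocorticoid-responsive genes (10.06), and high for Car3 (7.19), Adipoq (5.24) and the mean of endothelial markers (8.94). Knockout LPS array 2 was high for Nlrc5 (9.71) and low for Aplnr (5.54), Itgam (4.97) and Pde3b (5.52), and knockout LPS array 4 was low for Pde4b (9.08) and high for Mtr (7.82). The other wild-type LPS arrays stood out for C1ra (9.80, array 2), Icam1 (10.33, array 1), Mtr (5.28, array 3) and Isy1 (5.82, array 2). Wild-type saline arrays stood out for Saa3 (4.13, array 3), Casp4 (4.95, array 1), Myl7 (12.83, array 1), Ldb3 (11.96, array 2), Snhg11 (4.78, array 2), Gstp1 (12.18, array 2), Tslp (3.61, array 4), cardiac stress genes (mean 11.08, array 4) and atrial markers (mean 11.13, array 1). Knockout saline arrays stood out for Cfb (4.48, array 1), Emcn (9.07, array 1), Cidec (3.40, array 4), proteolysis and autophagy (mean 9.81, array 2), cell death genes (mean 6.50, array 1), macrophage markers (mean 6.98, array 2) and B cell markers (mean 4.51, array 4).

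The LPS responses of the genotypes differed by the interaction test for 6 lists, by a mean log2 difference of -0.397 for MHC class II, -0.164 for the tricarboxylic acid cycle, -0.088 for oxidative phosphorylation, 0.259 for immediate early genes, 0.609 for adipocyte markers and 1.385 for skeletal muscle markers. With an estimated correlation 0 of the 6 held, the skeletal muscle difference was -0.01 without wild-type saline arrays 1 and 4, and that of immediate early genes 0.016 without wild-type LPS array 4. The adipocyte difference lay mainly in the saline levels: wild-type and knockout means were 6.287 and 5.532 after saline and 4.857 and 4.711 after LPS. Among 10092 probe sets outside the gene tests, limma called 840 for LPS in wild-type and 1083 in knockout hearts, and 2 each for knockout against wild-type after saline, after LPS and on average.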

How the results depend on the processing

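The settings that leave out 2 arrays, and the lists under both rescalings, were chosen after seeing the data, and the others before the data were examined. The targeted receptor's own result was not run, and settings with only the arrays compared give no value for the averaged effect or the interaction. The precision is limited by 4 arrays per group and by signal near background, where Cidec lies. The LPS correlation of 0.921 stood at 0.916 to 0.938 where computed, outside the settings that leave out 1 array. It was not computed for every probe set by itself, the variance priors, only the arrays compared or the fold change limit. The interaction gave 0 genes in each setting run for it. Over settings other than those that leave out 1 array, named genes kept direction and side of the threshold in 2699 results, lost the call in 31, gained it in 25 and moved, passing in neither setting, in 5. For lists the numbers were 1975, 102, 50 and 127, with 8 reversed. With 1 array left out they were 3134, 33, 14 and 3 for genes, and 3656, 68, 101 and 205 with 2 reversed for lists. Where no cause follows from the setting's own construction, the cause was not tested.

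Every probe set by itself, which counts probe sets instead of genes, called 6590 for LPS in wild-type and 8394 in knockout hearts, and 3, 4 and 9 for the knockout effect after saline, after LPS and on average. With dim genes left out, which removes Cidec from the test, 0 were called after saline. With only the arrays compared 14 were called after saline and 0 after LPS. The replicate block called 2 on average, the second quantile normalization 4, and array weights 21 after saline and 11 on average. A fold change of at least 1.5 left 2247 and 2772 LPS genes by construction.

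Without the 2 LPS arrays of lowest weight, 5723 were called for LPS in wild-type hearts, 9 after saline and 7 on average. Without wild-type saline arrays 1 and 4 the counts were 2061 for LPS in wild-type, 0 after LPS and 0 on average, and without wild-type saline arrays 3 and 4 they were 2295, 0 after saline, 0 after LPS and 0 on average, in both cases with fewer arrays. Leaving out 1 array gave 3006 to 4902 genes for LPS in wild-type, 3871 to 5527 in knockout hearts, 1 to 5 after saline (5 without knockout saline array 3), 0 to 3 after LPS (0 without wild-type LPS array 2 or knockout LPS array 2 or 4), 1 to 3 on average, 0 for the interaction, and a correlation of 0.899 to 0.931.

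Reversed without the 2 LPS arrays of lowest weight were, for knockout against wild-type after LPS, complement (mean 0.043), calcium handling and ion channels (0.110), the tricarboxylic acid cycle (0.011), immediate early genes (-0.199) and fibroblast markers (0.312), for the average fibroblast markers (0.117), and for the interaction fibroblast markers (0.389) and immediate early genes (test down, mean 0.013). Without wild-type LPS array 4, immediate early genes reversed after LPS (-0.197) and in the interaction (test down, mean 0.016). With 1 array left out their means ran from -0.197 to 0.178 after LPS and from 0.016 to 0.391 in the interaction.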

Other observations

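The values in this part were singled out after they had been seen, and no test of them was planned.

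Atrial markers had a high list mean in tissue labelled ventricular myocardium, 11.63 in wild-type and 11.85 in knockout saline hearts. Their levels were uneven: Bmp10 stood at 4.578 to 6.744 in the saline arrays. Myl7 stood at 13.24 ± 0.27 (SD, n = 4) in wild-type and 13.37 ± 0.05 (SD, n = 4) in knockout saline hearts, and at 12.18 ± 0.37 and 12.19 ± 0.32 after LPS. The adipokine Adipoq stood at 8.12 ± 0.48 in wild-type and 6.79 ± 0.78 in knockout saline hearts, and at 3.84 ± 0.93 and 3.46 ± 0.16 after LPS. The adipocyte list mean was 5.26 in wild-type LPS array 4, and the lowest value among the knockout saline arrays was also 5.26.

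On unlogged values, wild-type LPS array 4 reached 90.7% of the mean rise of the other wild-type LPS arrays for Saa3, 74.2% for Lcn2, 71.9% for S100a8, 60.7% for S100a9, 42.4% for Cxcl9, 20.7% for Nfkbiz, 7.95% for Myc and 5.56% for Junb.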
